A study of Caenorhabditis remanei and Caenorhabditis briggsae and Caenorhabditis brenneri with 150 samples.

How the data were processed

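RNA of 5 nematode species of the genus Caenorhabditis (C. brenneri, C. briggsae, C. elegans, C. japonica and C. remanei) was measured on 150 one-colour Agilent arrays, 30 per species. Each species had its own array design of 43803 probes of 60 bases. Per the labels, embryos were taken out of adults at the 4-cell stage, kept until they reached a stage, and picked by eye, with 48 embryos per sample and independent biological samples for the 3 replicates of each stage. RNA was amplified by in vitro transcription, labelled with Cy3 and hybridised with an Agilent spike-in mix of 10 RNAs.

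The deposited series tables and scanner files hold intensity values on a linear scale, extracted per the file headers with Agilent Feature Extraction 10.5.1.1. The processed signal in the scanner files is an intensity after background subtraction and spatial detrending within the array, per the file headers, with no normalisation between arrays. The deposited tables equal the processed signal of the same array, with a largest relative difference of 0 over 6570450 values, so an alternative based on the authors' tables would repeat the same numbers and was not run. The mean spot intensity and the local background intensity, also deposited, served 1 alternative.

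Analysis used R 4.3.3, limma 3.58.1 and statmod 1.5.0, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, biopython 1.88, networkx 3.6.1 and BLAST+ 2.17.0 for tables and sequences and matplotlib 3.10.9 for plots. Spots that the extraction software marked as outliers were left out. The log2 processed signal was expressed relative to the array's 75th percentile over non-control probes. The probe with the highest mean stood for a gene. A gene was kept if it was well above background, by the software's own call, on all 3 replicates of at least 1 stage. Levels below are on this scale, so 0 is the array's 75th percentile. limma fitted 1 mean per stage to the 30 arrays of a species, with moderated variances that follow a trend in intensity, and p values were adjusted by Benjamini-Hochberg within each comparison. A gene rose or fell if its adjusted p was below 0.05 and its change at least 2-fold. The stage effect was limma's moderated F test over the 10 stage means.

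Comparisons were fixed before the data were examined. They were the stage effect, 3 intervals per species and the 9 steps between neighbouring stages. The intervals were early (stage 1 to 4), middle (stage 4 to 7) and late (stage 7 to 10). Stage alignment, similarity by stage and the difference between species in an interval change were planned only if the files linked genes between species. The links were built from the probe sequences, which that condition did not name. Stage 1 was the 4-cell embryo, 2 the division of the E cell, 3, 4, 5 and 6 the 4th, 5th, 6th and 7th division of the AB lineage, 7 ventral enclosure, 8 the comma stage, 9 the onset of movement and 10 the L1 larva. Steps were ranked by called genes within a species and compared by Kendall's W with a permutation test. Permutation tests used 100000 resamples, and the smallest p they can give is 1e-05.

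No file pairs probes with gene symbols. The gene table supplied as a reference covers C. remanei alone and holds locus tags without symbols. The 22 lists of gene symbols fixed before the data were examined could therefore not be applied. In their place, 16 sequence families were read from the translated probes by sequence pattern; they were chosen after the probe sequences were seen and before any expression values were compared. The frame was taken from the probe's position in its transcript. A stop codon lay inside the frame in at most 1.22% of a species' probes, against 55.8% to 57.9% in the next frame. A pattern in 60 bases finds only those members whose probe covers it, so family sizes are those of the probes. Families of at least 5 kept members were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the families of a species and interval. Each call is given with the adjusted p from an estimated correlation. Species not named for a family and interval had no call there or too few members. fry in limma, which asks whether the genes of a family move on balance in 1 direction, was run beside it.

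Genes of different species were linked by reciprocal best matches of the translated probes (blastp, expectation limit 0.001, at least 10 residues matched, at most 30 residues apart in position). Groups with 1 gene per species in all 5 numbered 4650, of which 4445 were kept in every species. Links join probes of similar sequence and are not a curated list of orthologues.

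Named genes follow a rule fixed before the data were examined: the largest fitted changes in each direction with adjusted p below 0.05, well above background on all 3 arrays of the higher stage, and with the 3 arrays of 1 stage all above those of the other. The rule asked for gene symbols in C. elegans and allowed at most 2 identifiers each way without them only in the other species. Without symbols, its other terms were applied to the identifiers of C. elegans too, which departs from the rule. For each direction 2 are given for C. elegans and 1 for the other species. The files do not pair these identifiers with names. Where the probe kept for the gene was not well above background on every array of the lower stage, only a lower bound of the fold change is given, with each array's signal raised to at least the lowest signal well above background on that array. The number of arrays on which that probe was well above background is given where it is not 0, and the number by any probe of the gene where it differs. The rule ranks fitted changes and not bounds, so a gene that it passed over can have a larger bound.

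The precision is limited by 3 arrays per stage. On data simulated with the spread of each species' arrays, the fits recovered 54% of 50 genes changed by 2 on the log2 scale in C. elegans and 26% in C. japonica, and 100% and 72% of those changed by 4. Wrong calls among the unchanged genes of a simulated species numbered 4 to 9. Few genes were changed in the simulation and arrays varied independently, without slides, whereas 22.5% to 63.0% of genes were called in the real intervals. The shares recovered and the wrong calls therefore need not hold for the real data. The sequence links were not part of that test.

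Alternatives were normexp background correction (offset 50), quantile normalisation, scaling on the spike-in probes, no detection filter, the mean of a gene's probes, no fold minimum, only the 6 arrays of an interval, slide as a fixed or a random block, the replicate number as a block, each replicate left out in turn, the mean absolute change per step, uncentred levels, Spearman correlation and the estimated correlation. Further alternatives were added after the data were seen: scan day as a fixed block, leaving out 3 C. japonica arrays that stand apart in the share of probes above background, other rules for links, and leaving out C. japonica. All samples were used.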

Results

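The 150 arrays covered 10 stages from the 4-cell embryo to the L1 larva in 5 Caenorhabditis species, with 3 independent samples of 48 embryos at each stage of each species. The arrays carried probes for 24695 genes of C. brenneri, 20294 of C. briggsae, 19052 of C. elegans, 21908 of C. japonica and 25895 of C. remanei. The share of probes well above background had a median of 78.7% in C. brenneri, 82.9% in C. briggsae, 75.8% in C. elegans, 77.7% in C. japonica and 74.8% in C. remanei. Single arrays ran from 47.9% in C. brenneri to 98.2% in C. japonica, and no probe was saturated. The 75th percentile of the processed signal lay between 376.8 and 3388 intensity units on single arrays, both of C. brenneri. Correlations across genes between replicates of a stage were 0.928 to 0.986 in C. brenneri, 0.945 to 0.982 in C. briggsae, 0.931 to 0.985 in C. elegans, 0.856 to 0.986 in C. japonica and 0.941 to 0.984 in C. remanei.

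The series asks how gene expression runs through embryonic development in related species, and the stage effect tested, in each species, which genes changed at all. Precursors of RFamide neuropeptides, short signalling peptides of neurons, had a median level in C. elegans of -4.14 ± 0.78 at the onset of movement and 0.38 ± 0.05 in L1 larvae (SD, n = 3). Collagens, which build the cuticle and basement membranes, had a median level in C. elegans of -5.19 ± 0.56 at the 4-cell stage, -0.80 ± 0.67 at ventral enclosure and 2.08 ± 0.84 in L1 larvae (SD, n = 3). Core histones, around which DNA is wound, had a median level in C. elegans of 4.55 ± 0.32 at the 5th AB division and 1.74 ± 0.32 at ventral enclosure (SD, n = 3). WD40 repeat proteins, scaffolds of many protein complexes, had a median level in C. elegans of 1.98 ± 0.22 at the 4-cell stage and -0.33 ± 0.08 in L1 larvae (SD, n = 3). The stage effect was called for 20778 of 21971 genes in C. brenneri (94.6%), 17189 of 18860 in C. briggsae (91.1%) and 15750 of 16980 in C. elegans (92.8%). It was called for 13253 of 18146 genes in C. japonica (73.0%) and 21507 of 22902 in C. remanei (93.9%). With slide as a fixed block the counts were 20282, 17399, 15945, 14219 and 21093, in the same order of species.

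**Figure D1:**
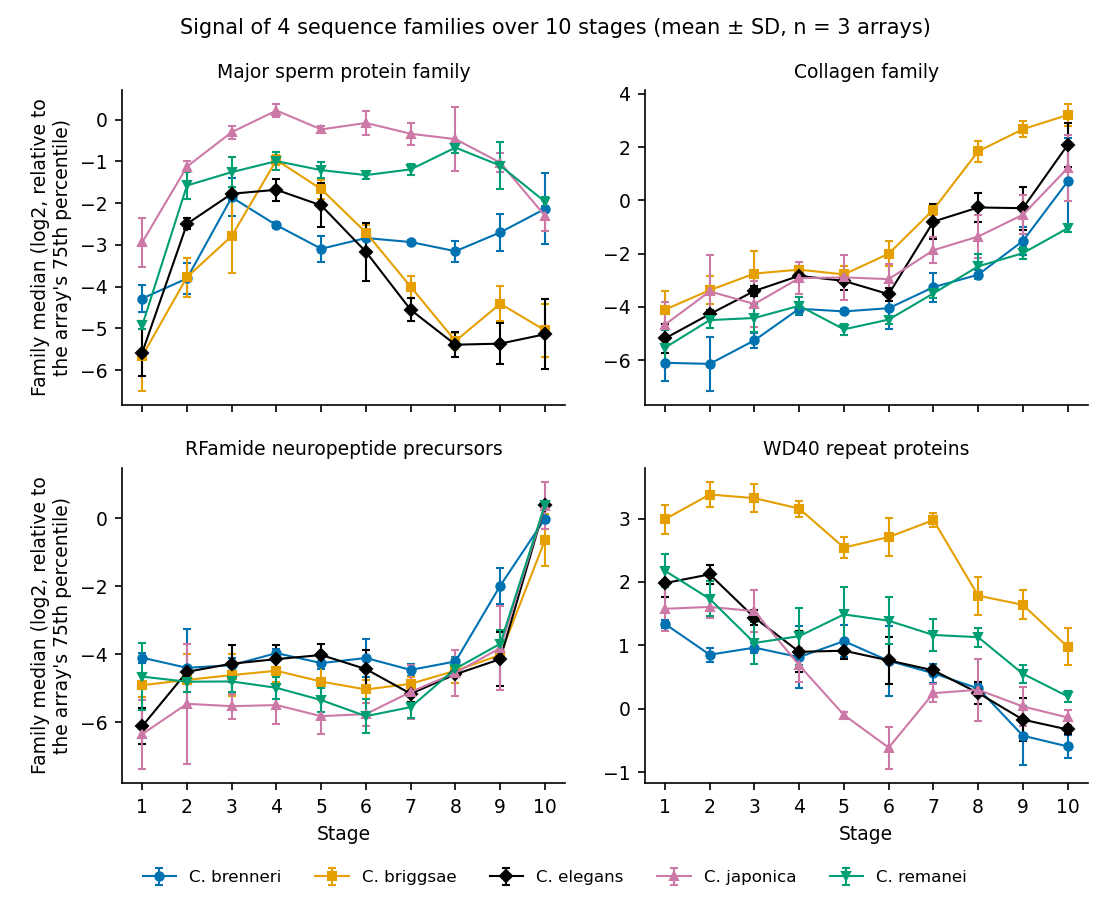
Median log2 signal, relative to the array's 75th percentile, of the measured members of 4 sequence families (y axes) against stage (x axes, 1 to 10) in 5 species; points are means of 3 arrays and bars their SD. The major sperm protein family is highest at stage 4 in C. elegans (-1.68) and C. briggsae (-0.97), and RFamide precursors in C. elegans reach 0.38 at stage 10.

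The early interval asks what changed between the 4-cell stage and the 5th AB division, when embryonic transcription adds to the RNA supplied by the mother. Genes of the major sperm protein family, cytoskeletal proteins of nematode sperm, rose together: 31 of 31 measured members rose over the 4 species tested. Only 21 of the 31 had a probe at least 10 bases different from every other probe of the family, so the number of separate genes is uncertain. Their median changes were 4.14 in C. elegans (12 of 12 members, adjusted p = 8.89e-05), 4.56 in C. briggsae (6 of 6, adjusted p = 0.000277), 3.15 in C. japonica (6 of 6, adjusted p = 1.27e-06) and 4.12 in C. remanei (7 of 7, adjusted p = 0.000181). With an estimated correlation these calls were lost, with adjusted p = 0.505, 0.991, 0.180 and 0.245 in that order. The 4 medians were 2.42 to 2.69 with normexp, 2.58 to 3.69 with quantile normalisation and 2.17 to 4.58 with spike-in scaling. C. brenneri had 4 measured members, too few for the test, with a median level of -4.28 ± 0.32 at the 4-cell stage and -2.53 ± 0.07 at the 5th AB division (SD, n = 3). Collagens rose in C. elegans by a median of 2.25, with 57 of 88 members up and 0 down (adjusted p = 8.24e-05; adjusted p = 0.505 with an estimated correlation), and of 1.01 with quantile normalisation, 1.28 with normexp and 1.22 with spike-in scaling. In C. briggsae their median was 1.37, with 44 of 82 up and 2 down (adjusted p = 0.000758; adjusted p = 0.991 with an estimated correlation), and the call was lost with quantile normalisation (median 0.58, adjusted p = 0.0657); with normexp the median was 0.59. The other 14 families were called in no species in this interval.

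Among single genes of C. elegans, C52E2.7 rose at least 3522-fold (adjusted p = 3.80e-21) and Y82E9BR.17a at least 3706-fold (adjusted p = 2.59e-23), both from no array above background at the 4-cell stage. F32D1.6 fell at least 196-fold (adjusted p = 1.16e-11) and was above background on 2 of 3 arrays at the later stage. T21C9.13 changed by -6.55 ± 0.41 on the log2 scale (SE, adjusted p = 8.95e-14) and had a linked gene in all 5 species. In the other species the rule picked rises of at least 2555-fold for CBN17873 and 3838-fold for CRE01255, and of at least 1424-fold for CBG11209 and 1460-fold for CJA10603, the last 2 above background on 1 of 3 arrays at the 4-cell stage. The falls it picked were -7.94 ± 0.55 SE for CBN12089 and -7.90 ± 0.67 SE for CRE06336 on the log2 scale, at least 52.7-fold for CJA05107 (above background on 1 of 3 arrays at the later stage) and at least 66.5-fold for CBG22677.

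In all, 8188 genes rose and 5643 fell in C. brenneri, 4824 and 4167 in C. briggsae, 5726 and 2183 in C. elegans, 2946 and 1135 in C. japonica, and 6839 and 5796 in C. remanei. With slide as a fixed block, 14031, 9280, 8269, 4515 and 13522 genes were called. Within a single scan day, C. brenneri had 13045 called genes on 14 arrays, 2 of them at each end of the interval. The changes correlated across genes with those of all arrays at r = 0.994, but the same arrays enter both, so a high r is built in. The other species had too few arrays of the stages in 1 scan day. The median change of all genes ran from -0.18 to 0.63 over the species, from -0.42 to 0.18 with quantile normalisation, from -0.73 to 0.93 with spike-in scaling and from -0.57 to 0.56 with normexp, so the balance of rises and falls depended on the scaling. The share rising of the called genes was 59.2% in C. brenneri, 44.6% with quantile normalisation and 77.0% with spike-in scaling. It was 53.7% in C. briggsae, 42.02% with quantile normalisation and 48.8% with normexp; 72.4% in C. elegans, 51.5% with quantile normalisation and 46.4% with spike-in scaling; and 54.1% in C. remanei, 46.03% with quantile normalisation, 49.5% with normexp and 41.8% with spike-in scaling. In C. japonica the count called fell to 948 with spike-in scaling and to 2229 without replicate 3, and was 3635 without the 3 arrays that stand apart.

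The middle interval covers the 5th AB division to ventral enclosure, when cell division slows and the epidermis closes over the embryo. Collagens rose in all 5 species. Their median changes were 0.85 in C. brenneri (29 of 68 members up and 5 down), 2.34 in C. briggsae (52 of 82 up and 5 down), 1.69 in C. elegans (46 of 88 up and 12 down), 1.08 in C. japonica (22 of 77 up and 4 down) and 1.13 in C. remanei (31 of 68 up and 10 down), with adjusted p of 0.000708 or less. The C. japonica call was lost with the mean of a gene's probes (median 0.63, adjusted p = 0.103). With an estimated correlation the adjusted p was 0.412 to 0.919, and no collagen call held. The medians were 0.31, 1.99, 0.96, 0.56 and 0.22 with normexp, and 1.61 to 3.09 with spike-in scaling, and that of C. japonica was 1.68 with slide as a fixed block. The major sperm protein family fell again in C. elegans (median -2.99, 12 of 12 members) and C. briggsae (median -2.82, 6 of 6), with adjusted p = 0.00054 and 0.00255. With an estimated correlation those calls were lost (adjusted p = 0.506 and 0.595), and the C. elegans median was -1.82 with spike-in scaling. In C. remanei the median level of this family was -0.996 ± 0.208 at the 5th AB division and -1.19 ± 0.13 at ventral enclosure, and in C. japonica 0.22 ± 0.15 and -0.34 ± 0.27 (SD, n = 3). Core histones fell in C. elegans (median -2.36, 6 of 7 members, adjusted p = 0.0170; adjusted p = 0.588 with an estimated correlation), with a median of -1.19 with spike-in scaling.

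Cytochromes P450, oxidising enzymes, rose in C. briggsae (median 1.69, 9 of 15 up and 2 down, adjusted p = 0.00356; adjusted p = 0.595 with an estimated correlation), with a median of 0.26 with normexp. Genes with an EGF-like repeat, an extracellular domain, were called up in C. elegans (median 0.70, 20 of 44 up and 6 down, adjusted p = 0.00054; adjusted p = 0.412 with an estimated correlation), but their median was -0.23 with normexp, 1.87 with spike-in scaling and 1.30 with slide as a fixed block. Homeobox, nuclear receptor or T-box genes, 3 kinds of transcription factor, had medians from -0.71 to 3.48 over the 5 species. They were called up only in C. remanei, with 4 of 11 up and 0 down and a median of 0.95 (adjusted p = 0.00552). Of 57 calls in 231 tests of families over all intervals, this was the single 1 that held with an estimated correlation (adjusted p = 0.0394), but it was lost with the mean of a gene's probes (median 0.88, adjusted p = 0.0535), and its median was 0.03 with normexp and 1.92 with spike-in scaling.

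The rule picked, in C. elegans, rises of at least 901-fold for D1086.12b (adjusted p = 4.36e-14) and at least 522-fold for C50F7.10 (adjusted p = 2.62e-13, its kept probe above background on 0 of 3 arrays at the 5th AB division and at least 1 of its 3 probes on 2). F45C12.11 fell at least 5589-fold (adjusted p = 6.46e-17) and C08E3.3 at least 3859-fold (adjusted p = 9.23e-15). Elsewhere CBN17717 rose at least 682-fold and CBG27198 at least 3134-fold, and CJA04931 at least 1399-fold and CRE29308 at least 1232-fold, the last 2 above background on 1 of 3 arrays at the 5th AB division. CBN01224 fell at least 641-fold, CRE22614 at least 1890-fold, CBG13193 at least 2661-fold and CJA12825 at least 407-fold. At ventral enclosure CJA12825 was above background on 2 of 3 arrays, as was CBG13193 by at least 1 of its 3 probes, though by its kept probe on 0.

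Between these stages 3600 genes rose and 5147 fell in C. brenneri, 3618 and 4446 in C. briggsae, 2765 and 5510 in C. elegans, 2557 and 2903 in C. japonica, and 3705 and 5289 in C. remanei. With slide as a fixed block, 7863, 7493, 7672, 5647 and 6354 genes were called, and no species had enough arrays of both stages within 1 scan day. Falls outnumbered rises in every species, and also with quantile normalisation, normexp and slide as a block. Spike-in scaling turned the share rising from 41.2% to 73.7% in C. brenneri, 44.9% to 68.6% in C. briggsae, 33.4% to 67.9% in C. elegans, 46.8% to 73.5% in C. japonica and 41.2% to 70.2% in C. remanei; with scan day as a block the share was 51.2% in C. japonica. The median change of all genes was -0.60 to -0.11 over the species, -0.25 to -0.07 with quantile normalisation, -0.74 to -0.22 with normexp and 0.42 to 0.81 with spike-in scaling. In C. japonica it was -0.11, but 0.18 with slide as a fixed block, 0.05 with slide as a random block and 0.06 with scan day as a block. In C. japonica 2204 genes were called with spike-in scaling and 3344 without replicate 3.

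The late interval runs from ventral enclosure to the L1 larva, through elongation, the onset of movement and hatching. RFamide neuropeptide precursors rose in all 5 species: 81 of 103 measured members rose and 3 fell, with median changes of 4.59 in C. brenneri to 5.76 in C. remanei and adjusted p of 0.00111 or less. With an estimated correlation none of these calls held (adjusted p 0.112 to 0.436). Collagens rose in all 5 species as well (226 of 383 members up and 27 down, medians 1.54 in C. elegans to 3.54 in C. brenneri, adjusted p of 0.00293 or less; adjusted p 0.291 to 0.436 with an estimated correlation). Their median was 3.01 in C. briggsae with spike-in scaling, against 1.899, and 1.11 in C. remanei with normexp, against 1.71. Cytochromes P450 rose in 4 of 4 species tested (38 of 55 members up and 4 down, medians 2.31 to 4.32, adjusted p 0.00293 to 0.0154; adjusted p 0.113 to 0.436 with an estimated correlation). In C. elegans their median of 4.32 was 2.12 with normexp and 2.64 with quantile normalisation.

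ABC transporters, membrane pumps, were called up in 5 of 5 species (33 of 50 members up and 6 down, medians 1.41 to 5.45, adjusted p 0.00832 to 0.0476; adjusted p 0.240 to 0.436 with an estimated correlation). The C. remanei call of ABC transporters was lost with slide as a fixed block (adjusted p = 0.0605), with slide as a random block (0.0519), with scan day as a block (0.0646), with the mean of a gene's probes (0.0511) and without replicate 3 (0.0855). The C. elegans call was lost with normexp (adjusted p = 0.0762), with the mean of a gene's probes (0.0672) and without replicate 1 (0.0728). In C. briggsae the median of 1.48 was 0.60 with quantile normalisation, 0.64 with normexp and 2.59 with spike-in scaling, and in C. japonica that of 1.41 was 0.85 with spike-in scaling and 0.64 with slide as a fixed block. Potassium channels rose in C. brenneri (median 5.58, 6 of 6), C. elegans (5.11, 5 of 6 up and 1 down) and C. briggsae (4.09, 4 of 7), with adjusted p = 0.0030, 0.0154 and 0.0165. With an estimated correlation these calls were lost (adjusted p = 0.0631, 0.113 and 0.435). Their median in C. briggsae was 1.67 with quantile normalisation and 1.83 with normexp, and in C. brenneri 3.62 with normexp. In C. remanei the median was 6.30, with 4 of 6 up and 1 down, and not called (adjusted p = 0.0786).

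Genes with a membrane-spanning segment were called up in all 5 species (1648 of 3870 up and 585 down, medians 0.50 to 1.18, adjusted p of 0.00797 or less; adjusted p 0.436 to 0.744 with an estimated correlation), but their medians were -0.22 in C. briggsae to 0.44 in C. brenneri with quantile normalisation, -0.02 in C. japonica to 1.62 in C. briggsae with spike-in scaling, and 0.13 in C. briggsae to 1.00 in C. elegans with normexp. EGF-like genes were called up in C. briggsae (median 2.08, 27 of 50 up and 7 down), C. elegans (2.31, 29 of 44 up and 8 down) and C. remanei (2.09, 22 of 38 up and 9 down), with adjusted p = 0.00384, 0.00844 and 0.0361, and adjusted p = 0.435, 0.240 and 0.436 with an estimated correlation. The C. remanei call was also lost with slide as a fixed block (adjusted p = 0.0742), with slide as a random block (0.0519), with scan day as a block (0.0646) and without replicate 3 (0.0592). The 3 medians were 1.15, 1.88 and 0.41 with normexp and 1.46, 1.17 and 0.98 with quantile normalisation, and that of C. briggsae 3.19 with spike-in scaling. Their medians were -0.08 in C. brenneri and 0.35 in C. japonica, neither called (adjusted p = 0.478 and 0.481). Immunoglobulin domain genes, many of which encode adhesion proteins, rose in C. elegans (median 3.74, 8 of 10, adjusted p = 0.0154; adjusted p = 0.157 with an estimated correlation).

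Other families fell. WD40 repeat genes fell in C. elegans (median -1.21, 9 of 17 down and 0 up, adjusted p = 0.0132; adjusted p = 0.112 with an estimated correlation) and C. briggsae (-1.55, 8 of 11 down and 0 up, adjusted p = 0.00809; adjusted p = 0.150 with an estimated correlation), where quantile normalisation also ended the call (median -1.14, adjusted p = 0.0585) and the median was -0.44 with spike-in scaling. RNA recognition motif genes, which bind and process RNA, fell in C. elegans (median -1.24, 4 of 8), C. briggsae (-1.20, 4 of 8) and C. japonica (-2.08, 3 of 5), with adjusted p = 0.0167, 0.0241 and 0.0377; with an estimated correlation the adjusted p was 0.157, 0.435 and 0.330, and quantile normalisation also ended each of these calls (median -0.68 in C. briggsae). Spike-in scaling ended those of C. briggsae (median -0.09, adjusted p = 0.285) and C. japonica (0.105), and in C. japonica slide as a fixed block (0.113), slide as a random block (0.0778), scan day as a block (0.0907), normexp (median -1.13, adjusted p = 0.0537) and leaving out replicate 1 (0.0790) or 2 (0.0822) did so too. C2H2 zinc finger genes fell in C. elegans (median -1.09, 24 of 42 down and 5 up, adjusted p = 0.00220) and C. japonica (-0.91, 9 of 27 down and 2 up, adjusted p = 0.0213), with adjusted p = 0.216 and 0.193 with an estimated correlation, and the C. japonica call was lost without replicate 2 (adjusted p = 0.0764). The C. elegans median was -0.57 with normexp and -1.64 with quantile normalisation, and that of C. japonica -1.48 with spike-in scaling. Core histones (median -1.82, 6 of 10, adjusted p = 0.0101) and the major sperm protein family (-1.97, 6 of 6, adjusted p = 0.00194) fell in C. japonica, with adjusted p = 0.407 and 0.330 with an estimated correlation. Over the species tested, the medians ran from -1.82 to 0.52 for core histones and from -1.97 to -0.43 for the major sperm protein family.

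The rule picked, in C. elegans, rises of at least 1426-fold for C18H9.6 (adjusted p = 5.0e-13, above background on 1 of 3 arrays at ventral enclosure) and at least 1009-fold for F08H9.6 (adjusted p = 3.42e-17). R07C3.11 fell at least 1806-fold (adjusted p = 7.53e-22), and Y41D4B.26 at least 1575-fold (adjusted p = 2.34e-12, above background on 1 of 3 arrays in L1 larvae). CBG01391 of C. briggsae, a member of the cytochrome P450 family, rose at least 4115-fold, and CBN03094 of C. brenneri at least 1479-fold. CJA07239 rose at least 4391-fold and CRE06416 at least 2078-fold, each above background by its kept probe on 1 of 3 arrays at ventral enclosure; at least 1 of the 3 probes of CJA07239 was so on all 3. CBG24814 fell at least 6846-fold and CRE05175 at least 2222-fold, and CBN01959 at least 1625-fold and CJA09292 at least 1303-fold, the last 2 above background on 1 of 3 arrays in L1 larvae.

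Counts of genes that rose and fell were 5951 and 6739 in C. brenneri, 5525 and 5899 in C. briggsae, 5522 and 4693 in C. elegans, 3473 and 3658 in C. japonica, and 7256 and 6515 in C. remanei. With slide as a fixed block, 11886, 11961, 10011, 7789 and 13537 genes were called. Within a single scan day, C. briggsae had 10173 called genes on 16 arrays, 2 of them at each end of the interval. The r across genes with the changes of all arrays was 0.991, but the same arrays enter both, so a high r is built in. The other species had too few. The share rising of the called genes was 48.4% in C. briggsae, 36.8% with quantile normalisation and 77.9% with spike-in scaling; 54.1% in C. elegans, 40.8% and 66.7%; and 52.7% in C. remanei, 40.3% with quantile normalisation, 46.7% with spike-in scaling and 48.9% with normexp. In C. japonica it was 48.7%, 54.6% with spike-in scaling and 52.3% with normexp. The median change of all genes was -0.35 to -0.06 over the species, -0.73 to -0.49 with quantile normalisation, -0.77 to 0.76 with spike-in scaling and -0.43 to 0.53 with normexp. In C. japonica 3882 genes were called with spike-in scaling.

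The steps between neighbouring stages show when in development most genes changed. The step from movement to the L1 larva changed 8280 genes in C. brenneri, 8324 in C. briggsae, 7484 in C. elegans, 3754 in C. japonica and 10648 in C. remanei, the highest count of any step in 4 species and the next to highest in C. brenneri, where the step from the 4th to the 5th AB division changed 9884. The RFamide precursors of C. remanei had a median level of -3.69 ± 0.39 before this step and 0.40 ± 0.07 after it, and those of C. brenneri -1.99 ± 0.53 and -0.01 ± 0.14 (SD, n = 3). Few genes changed from the E cell division to the 4th AB division in C. japonica (12), C. briggsae (337), C. remanei (539) and C. elegans (986), against 4330 in C. brenneri. The counts of C. japonica and C. briggsae for this step are in doubt: all 3 C. japonica arrays of the E cell division correlated best with the 4th AB division, and in C. briggsae 1 array of each of these stages correlated best with the other. So is that of C. brenneri, whose arrays of the E cell division had 47.9%, 63.1% and 70.4% of probes above background. The 6th to the 7th AB division changed 620 genes in C. brenneri, 1815 in C. briggsae, 1065 in C. elegans, 284 in C. japonica and 1836 in C. remanei. At the 7th AB division 1 array of C. brenneri and 1 of C. elegans correlated best with the 6th. In C. elegans another split of the 6 arrays of these stages called 852 genes, so its count is in doubt too. From the 7th AB division to ventral enclosure, where the collagens of C. elegans had median levels of -3.53 ± 0.25 and -0.80 ± 0.67 (SD, n = 3), 4656 genes changed in that species. The ranks of the 9 steps were alike between the 5 species beyond shuffled ranks (Kendall's W = 0.635, one-sided permutation p = 6.0e-05), with mean ranks, 1 being the most genes, of 3.8, 8.2, 4, 5.8, 7.6, 4.6, 3.6, 6.2 and 1.2 in order of development. The labels do not give the time between stages, so counts are per step and not per hour.

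**Figure D2:**
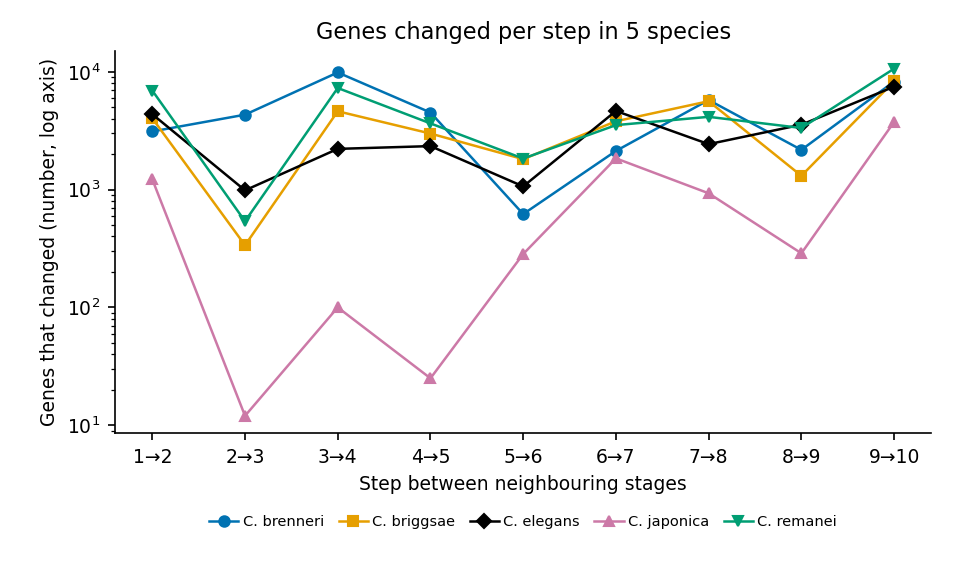
Number of genes that changed (y axis, log scale) in each of the 9 steps between neighbouring stages (x axis) in 5 species, 1 line per species. The last step holds 3754 to 10648 genes, and the step from stage 2 to 3 holds 12 to 4330.

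Linked genes were used to ask whether the same named stage held like expression in the 5 species. Levels relative to the gene's own mean were correlated across the 4445 linked genes for all pairs of stages. The mean r was 0.580 for the same stage and -0.05 for other stages, a difference of 0.630 (one-sided permutation p = 1e-05, the smallest that the permutations can give). Deviations from a gene's mean cancel over its stages, so a negative mean r for other stages largely follows from a positive one for the same stage. It is no separate evidence. The closest stage in another species was the same named stage in 156 of 200 cases (78%) and lay within 1 stage in 198 (99%). All 20 matches were to the same stage for ventral enclosure, movement and L1 larvae, against 7 of 20 for the 4th AB division and 12 of 20 for the 5th. Genes are not independent replicates, and the links rest on probe sequence.

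Similarity between species at each stage asks when in development the species are most alike. Relative to the gene mean, the mean r of the 10 species pairs was 0.610 at the 4-cell stage, 0.604 at the E cell division, 0.547 at the 4th AB division and 0.410 at the 5th. It was 0.446 at the 6th AB division, 0.493 at the 7th, 0.510 at ventral enclosure, 0.649 at the comma stage, 0.737 at movement and 0.792 in L1 larvae. With single arrays in place of stage means, the values had an SD between replicates of 0.0041 to 0.057. Without centring the order changed: the mean r was highest at the 7th AB division (0.795) and lowest in L1 larvae (0.719), with 0.787 at the 4-cell stage and 0.790 at ventral enclosure. Pairs share species, so no test was made.

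**Figure D3:**
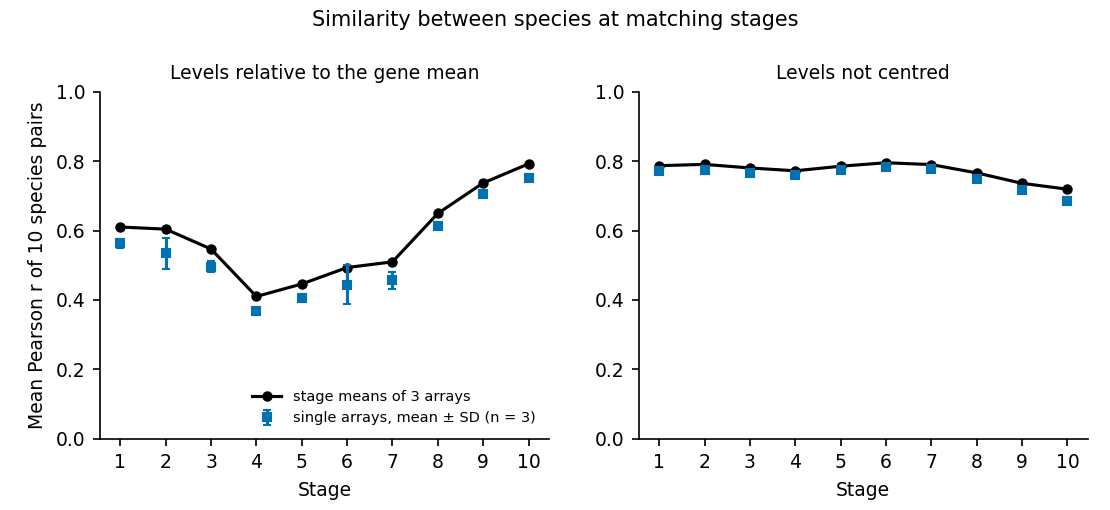
Mean Pearson r over the 10 species pairs (y axes) at each stage (x axes) across 4445 linked genes, with levels relative to the gene mean on the left and not centred on the right; black points are from stage means and blue points from single arrays (mean and SD, n = 3). Centred values are lowest at stage 4 (0.410) and highest at stage 10 (0.792), and uncentred values are lowest at stage 10 (0.719).

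The last comparison asks which linked genes changed alike in the 5 species and which did not. In the late interval 616 of the 4445 linked genes rose in all 5 species and 443 fell in all 5, against 9.28 and 6.99 if the calls of the species were independent. Among them, 10 of 15 linked RFamide precursors, 9 of 28 collagens and 70 of 269 membrane-spanning genes rose in all 5 species. In all 5 species 6 of 18 C2H2 zinc finger genes and 17 of the 269 membrane-spanning genes fell. Beside the 443 of all 4445 linked genes that fell, the first is a larger share and the second a smaller one. In the middle interval 173 rose and 40 fell in all 5 species (1.38 and 0.468 if independent), with 4 of 28 collagens among the rises. In the early interval 87 rose and 98 fell (1.43 and 2.19 if independent), and 0 of 28 collagens were among them. With so few shared changes among the 4445 linked genes, that 0 is not a result about collagens. Spike-in scaling and leaving out replicates moved several of these counts by over 1.5 times, for example the early falls to 20 and to 51.

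Examples chosen after their values were seen, named by the C. elegans identifier, are F37C4.6, which rose at least 58.4-fold in each species in the early interval, and T21C9.13, which changed by -6.87 in C. brenneri and -3.04 in C. japonica on the log2 scale (adjusted p of the species difference = 2.55e-05). The collagen F56D5.1 rose by 6.02 to 6.62 in the middle interval (adjusted p of the difference = 0.979). Y73C8B.4, a gene with an EGF-like repeat, changed by -4.93 to -2.61 in the same interval (adjusted p of the difference = 0.0681). C50F4.1 rose at least 276-fold and K08B4.2 fell at least 405-fold in each species in the late interval. The exact changes are of genes above background on all arrays of the lower stage in each species. A p above the threshold does not show equal changes.

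The change over the interval differed between species for 3634 linked genes in the early interval (81.8%), 3025 in the middle (68.1%) and 2304 in the late (51.8%). Rises in some species with falls in others were seen for 917, 710 and 240 genes in that order. Correlations of the changes across linked genes between 2 species had medians of 0.423, 0.453 and 0.763. With slide as a fixed block the difference was called for 3959, 2930 and 2864 genes. Each species had its own probes and slides, so a difference between species and a difference in how probes respond cannot be told apart for a single gene. Nor can a shift in staging: only 12 of 20 best matches of the 5th AB division were to the same stage. The fit also used a single spread per gene for all species. Yet the median SE of the early changes was 0.67 in C. japonica and 0.48 to 0.54 in the others, which can affect the counts.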

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

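No test in this part was chosen after its result was seen; the links between genes were drawn from probe sequences before any expression values were compared.

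The 3 results below stand out because the change over an interval differed between species by a test of the difference itself, limma's F test over the 5 species. In the early interval 3634 of 4445 linked genes differed. In the middle interval 3025 linked genes differed. In the late interval 2304 linked genes differed. Of the linked genes that changed alike in all 5 species, 132 differed in size early (87 rose and 98 fell), 179 in the middle interval (173 and 40) and 607 late (616 and 443). Over all linked genes the share that differed was 81.8%, 68.1% and 51.8%. Among genes that rose in some species and fell in others, 912 of 917, 702 of 710 and 239 of 240 differed. Those were chosen by opposite changes on the same arrays, so that result was largely fixed by the choice.

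Chance alone is an unlikely source of the full counts of linked genes that differed. Of 100 draws that exchanged arrays between species, the real one included, 1 gave as many genes in each interval. In that version, with missing spots filled by the stage mean, the real counts were 3635, 3012 and 2303 and the highest of the other draws 631, 22 and 86. The exchange carries differences between species and their slides into the spread within a group, which lowers the counts of the other draws. The draws therefore cannot tell how many single calls are right. With spike-in scaling 2480, 2060 and 1798 genes differed. Each species was measured on its own array design and slides, so a difference between species cannot be told apart from a difference in how the probes of 2 designs respond, and no explanation other than chance was tested for these counts. A shift in staging between species and the larger spread of C. japonica also stay open.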

How the results depend on the processing

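The alternatives added after the data were seen were scan day as a block, the 3 left-out C. japonica arrays, the other link rules and leaving out C. japonica. Of 615 values recomputed for the results that answer a comparison, 521 kept their direction and stayed within 1.5 times a count, past a test's threshold or within the spread between replicates. Kendall's W of the step ranks ran from 0.60 to 0.667 and the stage alignment difference from 0.613 to 0.682 over their alternatives, all past their thresholds. The genes that the rule picked, of which the text names a part, kept their direction and their side of the threshold in all 780 recomputed values. They were picked for the largest changes on the same arrays, so this does not speak for other genes.

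The cause of the moves below was not tested, except that leaving out replicates leaves 2 arrays per stage and so less power. With the estimated correlation the family calls went from 6 to 0 in the early interval, 11 to 1 in the middle and 40 to 0 in the late. With spike-in scaling C. japonica had 948, 2204 and 3882 called genes in the 3 intervals, and the linked genes changed in all 5 species were 21 that rose and 20 that fell early, 4 that fell in the middle interval and 147 that fell late. With slide as a fixed block, 25 linked genes fell in all 5 species in the middle interval. Leaving out 1 replicate gave 2229 to 3624 called genes in C. japonica early and 3344 to 3931 in the middle interval. It gave 44 to 78 linked genes that rose in all 5 species early, and 51 to 63, 22 to 32 and 279 to 354 that fell in the early, middle and late interval.

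The centred similarity by stage moved by more than the spread between replicates as follows. With Spearman correlation it was 0.639 at stage 1, 0.392 at stage 4, 0.417 at stage 5, 0.464 at stage 7, 0.594 at stage 8, 0.716 at stage 9 and 0.803 at stage 10. With the mean of a gene's probes it was 0.667 at stage 1, 0.589 at stage 3, 0.442 at stage 4, 0.483 at stage 5, 0.553 at stage 7, 0.681 at stage 8, 0.773 at stage 9 and 0.831 at stage 10. With normexp it was 0.671 at stage 1, 0.655 at stage 2, 0.605 at stage 3, 0.459 at stage 4, 0.486 at stage 5, 0.571 at stage 6, 0.570 at stage 7, 0.692 at stage 8, 0.773 at stage 9 and 0.813 at stage 10. With quantile normalisation it was 0.533 at stage 1, 0.528 at stage 3, 0.448 at stage 4, 0.477 at stage 5, 0.638 at stage 8, 0.719 at stage 9 and 0.760 at stage 10. With no detection filter it was 0.403 at stage 4, 0.438 at stage 5, 0.639 at stage 8 and 0.783 at stage 10. With links at any position it was 0.399 at stage 4, 0.435 at stage 5, 0.654 at stage 8 and 0.777 at stage 10, and with only groups in which all 10 pairs match, 0.626 at stage 1 and 0.801 at stage 10. Leaving out C. japonica gave 0.649 at stage 1, 0.569 at stage 3, 0.424 at stage 4, 0.471 at stage 5, 0.549 at stage 7, 0.671 at stage 8, 0.758 at stage 9 and 0.807 at stage 10. Leaving out 1 replicate gave 0.592 to 0.606 at stage 1, 0.525 to 0.537 at stage 3, 0.395 to 0.401 at stage 4, 0.430 to 0.439 at stage 5, 0.636 to 0.646 at stage 8, 0.726 to 0.735 at stage 9, 0.776 to 0.785 at stage 10. In each of these the lowest value was at stage 4 and the highest at stage 10. Without centring it was 0.787 at stage 1, 0.791 at stage 2, 0.780 at stage 3, 0.772 at stage 4, 0.785 at stage 5, 0.795 at stage 6, 0.790 at stage 7, 0.766 at stage 8 and 0.719 at stage 10, which changed the order.

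The estimated correlation, with which 1 of the 57 family calls held, is not among the values that follow. Of 741 recomputed values of called families, 707 kept the call and 31 kept the direction but lost it, among them RNA recognition motif genes in C. japonica, EGF-like genes in C. remanei and ABC transporters in C. elegans and C. remanei. The median changed sign in 3: -0.23 for EGF-like genes of C. elegans in the middle interval with normexp, and late membrane-spanning genes at -0.22 in C. briggsae with quantile normalisation and -0.0156 in C. japonica with spike-in scaling. The cause was not tested.

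With the replicate number as a replicate block, the stage effect was called for 21133, 17863, 15891, 14672 and 21801 genes in C. brenneri, C. briggsae, C. elegans, C. japonica and C. remanei, and Kendall's W was 0.635. Interval counts with the block were 14272, 9356 and 13211 in C. brenneri, 9522, 8565 and 11869 in C. briggsae, 8045, 8430 and 10341 in C. elegans, 5312, 6677 and 8201 in C. japonica, and 13012, 9354 and 14069 in C. remanei. The block ended the late calls of RNA recognition motif genes in C. japonica (adjusted p = 0.0502) and of EGF-like genes (0.0509) and ABC transporters (0.0615) in C. remanei. The labels call the samples independent. Of pairs of arrays with the same number, 40% to 86.7% had deviations from the stage mean that correlated above the limit used, 0.1. The main fits did not use the number as a block, and these shares are not a reason against one. Arrays with the same number still deviated together on average in every species (mean r 0.09 to 0.24). The lowest r of a same-number pair was 0.03 in C. briggsae and -0.52 to -0.17 in the other species. The mean r for other numbers, -0.12 to -0.04, is no separate evidence, because deviations from a stage mean cancel within the stage. Closest to their own number were 25 of 30 arrays in C. brenneri, 30 in C. briggsae and 28 in C. elegans. In C. japonica 21 were, and in C. remanei 18. The data thus show a structure by replicate number, clearest in C. briggsae, which the main fits leave out. Its cause was not tested. The symbol lists fixed beforehand and the authors' tables gave no alternative values, since no file holds symbols and the tables equal the processed signal. Signal over background limits the changes of dim genes, which are given as lower bounds.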

Other observations

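The test of the deviation size, the 3 tests on the major sperm protein family and the comparison of linked with unlinked genes were chosen after the results they bear on were seen.

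Families that the interval calls describe in part had their own courses over the 10 stages (median levels, mean ± SD of 3 arrays, no test). Homeobox, nuclear receptor or T-box genes of C. briggsae were at -2.38 ± 0.86 at the 7th AB division, 1.23 ± 0.28 at ventral enclosure and -2.93 ± 0.48 in L1 larvae. In C. elegans the same group was at -6.40 ± 0.42 at the 4-cell stage, -2.16 ± 0.34 at the 5th AB division, -4.54 ± 0.36 at the 7th and -0.94 ± 0.41 at movement. Core histones of C. briggsae were at 3.83 ± 0.24 at the 7th AB division and 1.65 ± 0.25 at the comma stage. Those of C. elegans were at 4.55 ± 0.32 at the 5th AB division and 1.35 ± 0.38 at the comma stage. Immunoglobulin domain genes of C. elegans were at -6.80 ± 0.04 at the 7th AB division and 0.50 ± 0.38 at movement, and those of C. remanei at -4.65 ± 0.96 and -0.31 ± 0.10. ABC transporters of C. remanei were at -3.93 ± 0.24 at the comma stage and 0.23 ± 0.44 at movement, while those of C. elegans were at -3.03 ± 0.23 at movement and 0.77 ± 0.60 in L1 larvae. Collagens were at 1.84 ± 0.39 in C. briggsae at the comma stage and at -0.27 ± 0.55 in C. elegans. Cytochromes P450 of C. briggsae were at -6.18 ± 0.29 at the 5th AB division and -1.71 ± 0.14 at the 7th.

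A hypothesis was that genes with no sequence link to another species gain on genes linked to all 4 others at the end of development. It failed: on all 3 arrays, the difference in mean log2 signal between these groups was higher in L1 larvae than at the 5th AB division in 0 of 5 species. The groups hold different probes, so the difference itself is not read as a difference in expression.

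The major sperm protein family rose early in 4 species, and 3 technical explanations were set against a biological one. A general rise of dim probes stays open: with near-identical members counted once, at most 1.57% of 10000 random sets of the same starting level had as large a median in any species, but up to 14.94% of single genes did, the limit if the members move as 1. Array scaling is argued against, since the smallest median over the species under quantile normalisation, normexp and spike-in scaling was 2.17 on the log2 scale. Probes shared between near-identical members stay open for the number of genes, since only 21 of 31 had a probe that differed by at least 10 bases from every other probe of the family. A change in the embryos themselves, such as in transcription, may also account for it and was not tested. RNA brought in by sperm would be present before the 4-cell stage. Each of the 31 members in the 4 species tested rose after that stage, by at least 2.69 on the log2 scale of the main fits. For these members, this argues against such RNA as the source of the rise. The members of C. brenneri were not part of this comparison.

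The ranks of the steps were alike between species, and slides were a technical explanation, since replicates of neighbouring stages were often on different slides. Steps that crossed more slides did not hold more called genes (Spearman rho = -0.0416 over 45 species-steps, one-sided permutation p = 0.608), and Kendall's W was 0.632 with slide as a fixed block, which argues against slides as the source. Unequal time between stages stays open, since the labels give no times, as does a biological difference between stages.

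The centred similarity between species was lowest at the 5th AB division and highest in L1 larvae. Its relation with the share of detected probes over the 10 stages had rho = 0.430 (permutation p = 0.218). Pearson's r was 0.431 (permutation p = 0.214), and 0.420 without the 2 stages farthest from the median. With no detection filter the highest and lowest stage were the same, but the filter chooses genes and does not alter the share detected. A relation of this size can be missed with 10 stages, so the share of detected probes stays open as a source. The similarity followed the size of the deviations from the gene mean (rho = 0.879, permutation p = 0.0016; r = 0.917, permutation p = 0.00018, and 0.789 without 2 stages), which is consistent with centring as a source of the profile, since stages far from a gene's mean carry more of its variance. The relation with the uncentred similarity had the other sign (rho = -0.612, permutation p = 0.0660; r = -0.776, permutation p = 0.0113, and -0.10 without 2 stages, so it rests on those stages). Adjusted over the 3 relations by Benjamini-Hochberg, the permutation p of r was 0.214, 0.00054 and 0.0169 in this order, and which stage is most alike remains open, since it depends on centring.

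Regrouped arrays gave a check on chance. For the stage effect, chance alone is an unlikely source of the full count in each species. Of 100 draws, the real one included, 1 gave as many genes. Regrouping carries differences between stages into the spread within a group, so the draws cannot tell how many single calls are right. The real counts were 20778 in C. brenneri, 17189 in C. briggsae, 15750 in C. elegans, 13253 in C. japonica and 21507 in C. remanei, and the highest of the other draws 3369, 1995, 2798, 1150 and 3339. For the intervals, 6 arrays allow 10 splits, too few for a share under 0.05. The real counts for early, middle and late were 13831, 8747 and 12690 in C. brenneri (highest other split 1, 0 and 9), 8991, 8064 and 11424 in C. briggsae (1, 1 and 12), 7909, 8275 and 10215 in C. elegans (5, 1 and 22), 4081, 5460 and 7131 in C. japonica (1, 0 and 3), and 12635, 8994 and 13771 in C. remanei (90, 1 and 0).

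The steps also allow 10 splits each, too few for a share under 0.05. Over the 9 steps, the highest other split was 2604 beside a real count of 4330 in C. brenneri, 852 beside 1065 in C. elegans and 1125 beside 6940 in C. remanei. In C. briggsae, 3 of the 10 splits, the real one included, gave at least as many genes from the E cell division to the 4th AB division as the real one (highest other 858, real 337). This leaves the count of 337 in doubt, and its cause was not tested. There, 1 array of the E cell division correlated best with the mean of the 4th AB division (r = 0.973 against 0.968) and 1 array of the 4th AB division with the mean of the E cell division (r = 0.971 against 0.968). In C. japonica the real count from the E cell division to the 4th AB division was 12 and the highest other 10. In the same species, 2 splits gave as many genes from the 4-cell stage to the E cell division (highest other 1422, real 1223) and from the comma stage to movement (705, real 288), and these steps include arrays that stand apart in the share of probes above background.

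The number of arrays that correlated best with the mean of another stage was 1 of 30 in C. brenneri, 2 in C. briggsae, 1 in C. elegans, 10 in C. japonica and 0 in C. remanei, each time a neighbouring stage. The consensus correlation of arrays on the same slide was 0.321, 0.356, 0.264, 0.469 and 0.320 in the same order of species.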
